A study of Homo sapiens with 4 samples.

How the data were processed

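Cells of both lines, with or without 1 day in 10 nM estradiol, gave total RNA that was extracted with TRIzol, and libraries were made by an NEB method, per the labels' protocols; whether strand was kept is not given in the sources used here. Reads were aligned with HISAT2 and counted per gene with featureCounts, per the submitters' processing notes, with versions not given in the sources used here. The deposited table holds raw counts per gene for the 4 libraries, as whole numbers with no normalization, for 58336 genes. How reads matching several places were counted is not given in the sources used here, so genes with near-identical copies carry uncertain counts.

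The submitters' processing notes name the build hg18. The gene coordinates in the deposited table are not those of that build: 58216 of the gene IDs are in GENCODE release 29 on GRCh38, and for 57475 of these the start and end are equal to the file's, as are 57353 names. 120 IDs were not found there. Coordinates are therefore printed as the deposited table gives them, and are GRCh38 positions where they equal that annotation. Gene symbols are those of the file, which keeps some older names such as CTGF and CYR61.

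Samples were grouped by the treatment label into control and estradiol, with 2 libraries each. The number in the library name marks the cell line, 1 for AGS and 2 for HGC-27, so that libraries with the same number come from the same line and are paired. The 2 libraries of a line correlated at 0.997 in each line (Pearson r of log2 CPM plus 1 across tested genes), and libraries of different lines at 0.78. The line was a block in the main model, because each line was measured with and without estradiol; this model was fixed with the gene lists, the alternatives and the rule for named genes before the data were examined.

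Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, the filterByExpr filter, and a quasi-likelihood F-test in a model of cell line plus treatment, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 18278 genes, of which 13839 were protein coding and 1356 pseudogenes; they held 99.86% to 99.9% of the counts of each library. The model leaves 1 residual degree of freedom, the prior degrees of freedom were 396.9 and the biological coefficient of variation was 4.59%. Standard errors were derived from the log2 change and its F statistic. CPM were computed with TMM-scaled library sizes, and 3 counts correspond to 0.104 to 0.12 CPM. Within a line, where no test is possible, the log2 ratio of estradiol over control was taken with a prior of 0.5 counts and given with an exact conditional binomial counting interval of 95%. Reads without molecular identifiers are not independent molecules, so these intervals and bounds cover counting error only.

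A set of 37 gene lists was tested with camera (limma 3.58.1) on voom values of the same model, with a preset correlation of 0.01; the estimated correlation and fry were run beside it. Within a line, the median ratio of a list's members with a mean count of at least 10 was placed among 10000 random lists of the same size and matched expression, as a description. Lists with fewer than 5 measured members in a line were left out there.

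Genes were named by rule. For estradiol these were the 10 largest changes in each direction among calls with the same sign in both lines and a mean CPM of at least 1, filled where fewer passed with genes of the same sign and a mean count of at least 100 by the smaller of the line ratios. For each line they were the 6 highest and 6 lowest ratios at a mean count of at least 100, and for the line comparison the 10 largest differences in each direction at a mean CPM of at least 20. Up to 4 members per list and ESR1, ESR2, GPER1, GREB1, PGR and TFF1 were also named; only protein-coding and long noncoding genes entered the rule. Some genes that the rule picked are not reported here. The other called genes are named because few passed, and were chosen after their values were seen.

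The steps were tested on data simulated from these libraries. For estradiol, with 18460 simulated genes tested, edgeR recovered 22 of 50 genes changed 1.25-fold, 39 of 50 at 1.5-fold, 43 of 50 at 2-fold and 50 of 50 at 4-fold, with 4 false calls among 18260 unchanged genes. DESeq2 1.42.0 recovered 16, 23, 27 and 39 of 50 with 33 false calls, and voom 0, 9, 26 and 40 with 0. For the line comparison, with 17817 genes, edgeR recovered 23, 37, 46 and 50 of 50, with 7 false calls among 17617. Of lists within HGC-27, 3 of 3 shifted by 0.2 log2 lay above the 97.5th percentile, and 4 of 33 other lists lay outside the central 95%. Genes that the other lists share with the shifted lists were shifted too, such as POSTN, LUM and DCN of the fibroblast list. The 4 of 33 is therefore not a rate for unchanged lists. All simulated genes were drawn independently with a common spread, and the estradiol gene changes were the same in both lines. The measured ratios differed between the lines, so these recovery and false-call rates do not carry over to the estradiol calls.

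Alternatives were DESeq2 size factors, library totals, no filter, a mean CPM of at least 1, DESeq2 and limma-voom, no replicate block, other count minimums, a prior of 5 counts, and either line alone. Alternatives added after seeing the data were leaving out genes that share at least 50% of the 31-base stretches of their longest transcript with transcripts of another gene (GENCODE 29, Python 3.11.15), and the agreement of the lines over genes with at least 100 mean counts in each.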

Results

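The series measured gene expression by RNA sequencing in 2 human gastric cancer cell lines, each kept without added hormone and treated with 10 nM estradiol, the main oestrogen, for 1 day. AGS is an epithelial gastric adenocarcinoma line, and HGC-27 is an undifferentiated gastric carcinoma line. There were 4 libraries: 1 control and 1 estradiol library of AGS, and 1 control and 1 estradiol library of HGC-27. The deposited gene counts summed to 26306803 in AGS control, 28062811 in AGS estradiol, 28734374 in HGC-27 control and 24597379 in HGC-27 estradiol. Mitochondrially encoded genes took 7.94%, 7.82%, 7.91% and 7.88% of these counts. The design allowed a comparison of estradiol with control over both lines (n = 2 libraries per group, paired by line), a comparison of the lines with each other (n = 2 libraries per line), and a description of the estradiol response within each line, where no replicate existed. Nothing in the labels says that libraries came from independent experiments, so p-values speak of these libraries alone. With 1 residual degree of freedom per gene, p-values and SEs rest almost wholly on a spread pooled over genes, and a gene can have a small SE while its ratios in the lines differ. Intervals within a line are 95% counting intervals and cover counting error only.

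The receptors of estradiol and its best-known target genes came first. ESR1, the classical nuclear oestrogen receptor, had 4 and 5 counts in the control and estradiol libraries of AGS and 1 and 3 in those of HGC-27, so it was barely detected in any library. ESR2, the second nuclear receptor, had 44 and 73 counts in AGS and 17 and 19 in HGC-27. GPER1, the membrane oestrogen receptor, had 35 and 28 counts in AGS against 1051 and 894 in HGC-27, a fitted log2 difference of -4.93 ± 0.16 (SE) for AGS minus HGC-27. The glucocorticoid receptor NR3C1 was higher in AGS by a log2 difference of 8.38 ± 0.25, past the threshold in edgeR. Of the target genes, PGR had 0 counts in all 4 libraries. TFF1, a mucosal peptide, had 593 and 506 counts in AGS and 0 in HGC-27. GREB1 had 16 and 32 counts in AGS and 27 and 17 in HGC-27. None of ESR2, GPER1, GREB1 and TFF1 passed the test with estradiol over both lines. Of 37 tested members of the list of classical oestrogen-induced genes of breast cancer cells, 0 passed the test over all genes and 0 when adjusted over the list alone. The median log2 change of that list was 0.02 (camera adjusted p = 0.679).

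The first tested comparison asked which genes changed with estradiol on average over the lines. Of 18278 genes tested, 28 passed an adjusted p of 0.05 (edgeR quasi-likelihood test with the line as a block, Benjamini-Hochberg), 21 higher and 7 lower with estradiol. An unadjusted p under 0.05 was seen for 593 (3.24%), below the share of 0.05 that uniform p-values would give. The called genes included several that low oxygen is known to induce. Among these were NDUFA4L2, which lowers the activity of the respiratory chain (ENSG00000185633, chromosome 12, 57234903 to 57240715, log2 change 1.21 ± 0.18 SE, adjusted p = 1.92e-07), carbonic anhydrase CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159, 1.60 ± 0.37, adjusted p = 0.0185, with 2 and 0 counts in AGS and 0.12 in DESeq2), and NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022, 0.81 ± 0.10, adjusted p = 8.75e-11, but 0.00 in AGS alone). Others were the glycolytic enzymes ENO2 (0.55 ± 0.12) and ALDOC (0.48 ± 0.11, but -0.78 in AGS alone), and the secreted hormone STC1 (0.99 ± 0.21, with 3 and 0 counts in AGS and -0.39 in DESeq2). The neuronal membrane protein NRN1 rose by 0.89 ± 0.13, the growth factor binding protein IGFBP5 by 0.71 ± 0.14 and the scaffold protein PPFIA4 by 0.69 ± 0.12 (0.00 in AGS and 0.99 in HGC-27). The collagen-modifying enzyme PLOD2 rose by 0.34 ± 0.08, with 0 counts in both AGS libraries and 0.16 in DESeq2. The glucose transporter SLC2A3 rose by 0.25 ± 0.06 (0.36 in AGS and 0.11 in HGC-27). Also higher were the YAP target genes ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276, 0.62 ± 0.13, but -0.57 in HGC-27 alone) and CTGF (0.36 ± 0.08, but -0.05 in HGC-27 alone), the immediate-early gene IER3 (0.44 ± 0.10), PHLDB2 (0.34 ± 0.07) and the keratin KRT80 (0.33 ± 0.08, with 0.49 in AGS and 0.06 in HGC-27). IER3 stood at 0.22 in AGS and 0.80 in HGC-27, and PHLDB2 at 0.38 and 0.20. Lower genes included lysozyme, LYZ (ENSG00000090382, chromosome 12, 69348341 to 69354234, -0.43 ± 0.08, adjusted p = 0.000208), and the chloride channel CFTR (-0.44 ± 0.11, but 0.07 in HGC-27 alone). The fibrinogen chain FGB was also lower (-1.01 ± 0.22), with 0 counts in both HGC-27 libraries.

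The remaining calls were 9 genes that shared at least 50% of the 31-base stretches of their longest transcript with another gene, and their counts are uncertain because reads can fall on either copy. U2AF1, a splicing factor (chromosome 21, 43092956 to 43107587), fell by 0.98 on the log2 scale (SE 0.19), while its near-identical copy U2AF1L5 (chromosome 21, 6484623 to 6499261) rose by 1.09 (SE 0.16). The translation factor subunit EIF3C (chromosome 16, 28688558 to 28735730) rose by 0.63 ± 0.06 (1.09 in AGS and 0.23 in HGC-27). CCZ1B rose by 0.32 ± 0.08 (0.09 in AGS and 0.56 in HGC-27). The other 5 were the pseudogenes MEMO1P1 (1.94 ± 0.30), MTCO1P12 (0.55 ± 0.13), GTF2IP1 (-0.77 ± 0.10) and SMG1P2 (-0.92 ± 0.19) and the clone-named AC211486.3, which had 11 and 14 counts in the controls and 0 in both estradiol libraries. MTCO1P12 stood at 0.85 in AGS and 0.21 in HGC-27, and GTF2IP1 at -1.34 and -0.29. Genes with this much shared sequence were 32.1% of the calls and 8.92% of the tested genes, a measure chosen after such genes were seen among the calls.

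Few of the calls were seen in both lines. Of the 28 called genes, 18 had ratios of the same sign in both lines, but the counting interval excluded 0 in the same direction in both lines for 9. These 9 were EIF3C, U2AF1L5, U2AF1, GTF2IP1, SMG1P2, MEMO1P1, IER3, SLC2A3 and AC211486.3. Of the 9, 7 were genes of shared sequence. The interval excluded 0 in AGS alone for 8 genes and in HGC-27 alone for 10, and ALDOC went in opposite directions. For 9 calls the gene had a mean of over 100 counts in 1 line and under 10 in the other. NDUFA4L2 had 1 and 4 counts in AGS against 410 and 813 in HGC-27, IGFBP5 had 5 and 7 against 841 and 1196, and ENO2 had 6 and 8 against 1185 and 1506. LYZ had 6329 and 5004 counts in AGS and 2 and 0 in HGC-27. Fewer than 10 genes with the same sign in both lines fell past the threshold, and the genes of the same sign that the naming rule added below them were NAAA (-0.61 in AGS, -0.70 in HGC-27), NR5A2 (-0.48, -0.54), ANKRD39 (-0.54, -0.48), LYPD6B (-0.48, with 5 and 0 counts in HGC-27), FAM222A (-0.47, -0.55), TSPAN1 (-0.46, -0.93), RAP1GAP (-0.40, -0.83) and CASP10 (-0.38, -0.41), which are values and not calls. The counting intervals excluded 0 in both lines for ANKRD39 and RAP1GAP alone. ANKRD39 also shared 59.1% of its sequence with another gene. The number of calls depended on the test. Fitted without the line as a block, 0 genes passed in either direction (2 with an unadjusted p under 0.05). DESeq2 called 1 gene that edgeR had not (ITPR3, named after its value was seen; 145 genes under 0.05), and limma-voom called 0 (490 under 0.05). With 1 residual degree of freedom per gene, the spread was borrowed across genes, and leaving out the genes of shared sequence left 2 calls, NDUFA4L2 and NRN1, as the prior degrees of freedom fell from 396.9 to 20.6. NRN1 had 0 counts in both AGS libraries, so that both calls rest on HGC-27. The log2 changes themselves stayed near their values in that fit, as for NDRG1 (0.82), PPFIA4 (0.71) and LYZ (-0.43).

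Across all genes the ratios of the lines showed no linear relation, and slightly more genes moved in opposite directions than in the same direction. Over 11952 genes with a mean count of at least 100, the log2 ratios of AGS and HGC-27 had a Pearson r of -0.01 and a Spearman rho of -0.04 across genes, which are not independent replicates, and 48.1% of genes (95% binomial interval 47.2% to 49.0%) had the same sign in both lines. Ratios were small in each line: 10 genes of 10917 in AGS and 10 of 11663 in HGC-27, with a mean count of at least 100 in the line, differed more than 2-fold. Among 9867 genes with at least 100 mean counts in each line, the counting intervals excluded 0 in both lines for 312 genes in the same direction and for 480 in opposite directions.

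**Figure D1:**
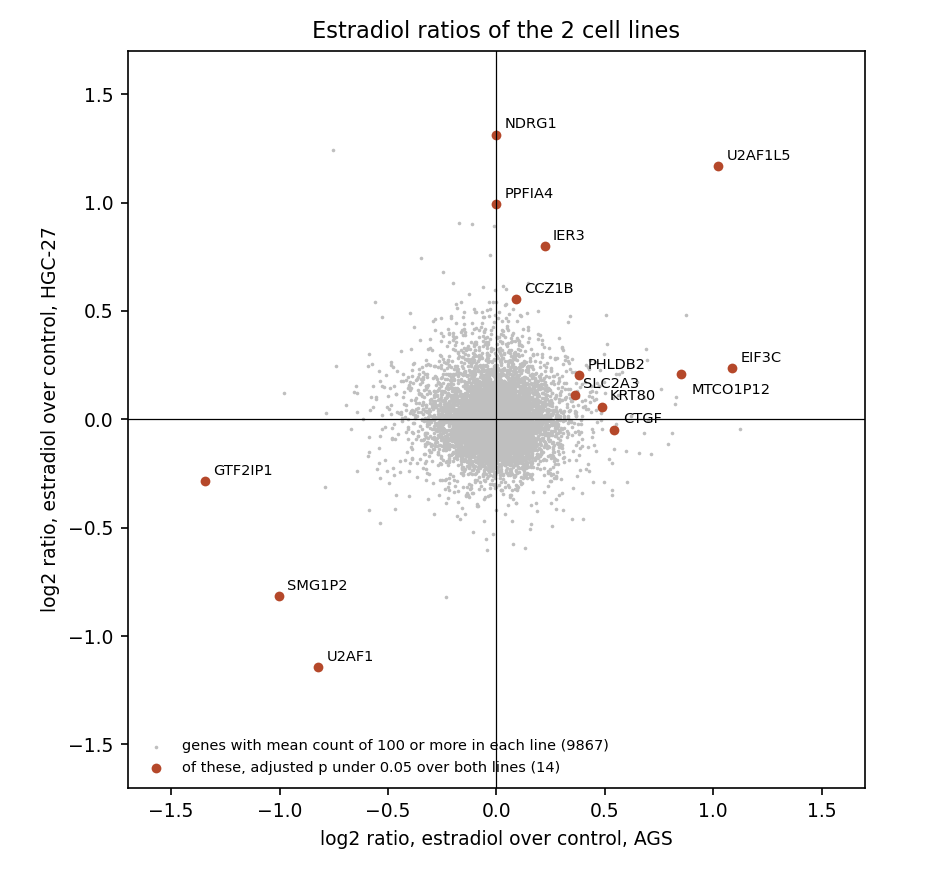
Log2 ratio of estradiol over control in AGS (horizontal axis) and HGC-27 (vertical axis), 1 point per gene, for 9867 genes with a mean count of at least 100 in each line; the 14 named points passed the test over both lines. The cloud shows no slope, NDRG1 lies at 0.00 in AGS and 1.31 in HGC-27, and U2AF1 and U2AF1L5 lie at opposite ends.

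Gene lists fixed in advance gave 7 lists higher and 11 lower with estradiol out of 37 (camera with a preset correlation of 0.01, adjusted p under 0.05). Glycolysis and hypoxia genes stood first: 32 of 34 had a fitted change above 0, 5 passed the test over all genes (CA9, NDRG1, ENO2, ALDOC and SLC2A3) and 13 when adjusted over the list alone, with a median log2 change of 0.14 (adjusted p = 3.58e-13). With the correlation estimated from the data (0.326) the camera adjusted p of this list was 0.599, and none of the 7 higher lists held. YAP and TEAD targets, which respond to cell tension and density, had 2 of 20 called (ANKRD1 and CTGF) and a median of 0.06. MAPK and immediate-early genes had 1 of 22 called (IER3) and a median of 0.10. Mesenchymal genes (median 0.08 over 42 members, COL4A1 at 0.74 ± 0.35), ATF4 targets induced by amino acid starvation (0.04 over 31, INHBE at 0.58 ± 0.20), fibroblast and endothelial markers (0.17 over 9) and NF-kB genes (0.08 over 24, CXCL2 at 1.20 ± 0.61) were higher as lists with 0 members called over all genes. ATF4 targets were higher as a list in HGC-27 alone (median log2 ratio 0.11). In AGS their median was -0.01, inside the range of random lists, with 3 counting intervals above 0 and 4 below. Adjusted over the list alone, 3 mesenchymal genes, 3 ATF4 targets, 4 MAPK genes, 2 YAP targets and 1 fibroblast marker were higher.

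None of the 11 lower lists held with an estimated correlation either, and they had 1 called member among them. They were targets of the aryl hydrocarbon receptor (median log2 change -0.12 over 8), genes of oestrogen synthesis and inactivation (-0.11 over 19), gastric and intestinal identity genes (-0.09 over 34), endoplasmic reticulum chaperones (-0.04 over 23), heat shock genes (-0.04 over 20), autophagy and lysosome genes (-0.04 over 30), NRF2 and glutathione genes (-0.03 over 26), ribosome biogenesis factors (-0.03 over 36), nuclear respiratory chain genes (-0.03 over 82), cytosolic ribosomal proteins (-0.02 over 85) and leukocyte markers (-0.30 over 5). Ribosome biogenesis factors were lower in HGC-27 alone (median log2 ratio -0.13, against 0.06 in AGS). Heat shock genes were also lower in HGC-27 alone (-0.07, against 0.005 in AGS, with 6 counting intervals above 0 and 3 below in AGS). Cytosolic ribosomal proteins lay inside the range of random lists of matched expression in both lines. Their median was -0.002 in AGS (range -0.008 to 0.025) and -0.03 in HGC-27. In HGC-27 that range was itself below 0 (-0.04 to -0.01), so the list did not stand apart from genes of like expression. The called member of the 11 lists was LYZ, listed as a leukocyte marker and also made by stomach epithelium. Adjusted over the list alone, 1 aryl hydrocarbon receptor target and LYZ were lower. The other 19 lists, among them the S phase, G2 and M phase, p53, interferon and cholesterol lists, were not called, with adjusted p-values from 0.0523 to 0.952; ENO2 is also a member of the neuroendocrine list among them. Of the 18 called lists 0 held with an estimated correlation, which gave adjusted p = 0.599 to 0.689, or with fry, which asks whether a list's genes move on balance 1 way, or without the block. The estimated correlation rests on 1 residual degree of freedom and found 0 of 3 shifted lists in data simulated for this comparison, where the preset correlation found 3 of 3. The simulated genes were drawn independently, so this check cannot show whether the preset correlation gives false calls for lists whose genes move together. Fry was not tried on simulated data. For epithelial junction and keratin genes between the lines, with a median log2 difference of 7.20, its adjusted p was 0.0359. The fit without the block takes the line difference into the spread. Fry and that fit can therefore hardly tell lists of small change from lists without change.

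In HGC-27, the estradiol library differed from the control library in groups that included genes of low oxygen, amino acid starvation and ribosome building. Of 34 glycolysis and hypoxia genes, 30 had a counting interval above 0 and 2 below, with a median log2 ratio of 0.23 that exceeded all 10000 random lists of matched expression. CA9 stood at 1.72 (interval 1.34 to 2.12), NDRG1 at 1.31 (1.19 to 1.44), the sterol regulator INSIG2 at 0.90 (0.69 to 1.12) and the glycolytic regulator PFKFB4 at 0.90 (0.68 to 1.12). ATF4 targets had a median of 0.11, with 18 of 31 intervals above 0, led by INHBE at 0.57 (0.39 to 0.76), DDIT4 at 0.54 (0.47 to 0.62) and asparagine synthetase ASNS at 0.28 (0.06 to 0.50). Mesenchymal genes had a median of 0.06, with 17 of 40 intervals above 0 and the collagen cross-linking enzyme LOXL2 at 0.33 (0.24 to 0.41). Ribosome biogenesis factors lay at -0.13, with 30 of 36 intervals below 0, below all random lists; NOP2 stood at -0.96 (-1.64 to -0.33) and RRS1 at -0.23 (-0.35 to -0.11). Lists outside the central 95% of random lists also included ferroptosis and iron genes (median 0.07, with 3 intervals above 0 and 3 below), apoptosis regulators (0.07, 2 above and 4 below), fibroblast and endothelial markers (0.12), cholesterol synthesis genes (0.04) and fatty acid synthesis genes (0.03) on the higher side, and nuclear respiratory chain genes (-0.05), heat shock genes (-0.07) and replication-dependent histones (-0.17) on the lower side. In all, 12 of 36 lists fell outside, where 1.8 would by chance if the genes of a list varied independently of each other. Lists whose genes move together fall outside more often. In data simulated for this line with independent genes, 4 of 33 lists that were not shifted as a whole fell outside. Some of these 33 share genes with the shifted lists, so this is not a rate for unchanged lists. The 6 highest ratios belonged to CA9, NDRG1, GPR89B (1.24), the clock-linked receptor RORA (1.24), NDUFA4L2 (1.20) and U2AF1L5 (1.17), and the 6 lowest to U2AF1 (-1.14), NPIPB4 (-0.82), ZNF667 (-0.70), SMN1 (-0.60), KBTBD4 (-0.59) and FSTL5 (-0.59). GPR89B, NPIPB4, SMN1 and KBTBD4 shared at least 50% of their sequence with another gene, so their counts are uncertain. With 1 library per treatment these differences have no replicate check, and 26.1% of all HGC-27 genes with a mean count of at least 100 lay beyond counting error (30.3% in AGS).

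In AGS, the estradiol library differed from its control in groups that included YAP targets, ribosome biogenesis factors and genes of cholesterol synthesis. YAP and TEAD targets had a median log2 ratio of 0.23, above all 10000 random lists, with 14 of 16 counting intervals above 0 and 1 below. In HGC-27 their median was -0.01 over 20, inside the range of random lists, with 1 interval above 0 and 3 below. AXL, a receptor kinase, stood at 0.95 (0.43 to 1.51), ANKRD1 at 0.82 (0.69 to 0.95), CTGF at 0.54 (0.47 to 0.62) and CYR61 at 0.33 (0.14 to 0.53). NF-kB and inflammatory genes had a median of 0.15 over 23 (0.09 over members with at least 100 counts), with the chemokines CXCL8 at 1.36 (0.13 to 2.91) and CXCL2 at 1.20 (0.61 to 1.86). MAPK and immediate-early genes had a median of 0.08 over 22, with 8 intervals above 0 and 0 below, FOSB at 0.56 (0.14 to 1.00) and DUSP4 at 0.32 (0.26 to 0.37); the median in HGC-27 was also 0.08, but inside the range of random lists, with 4 of 18 intervals above 0 and 1 below. Ribosome biogenesis factors lay at 0.06, with 19 of 36 intervals above 0 and 0 below. On the lower side, cholesterol synthesis and uptake genes had a median of -0.11, with 13 of 26 intervals below 0 and 0 above, and HMGCS1 at -0.32 (-0.40 to -0.24). Autophagy and lysosome genes lay at -0.08 (10 of 29 intervals below 0, WIPI1 at -0.54) and gastric and intestinal identity genes at -0.08 (13 of 33 below 0, FOXA2 at -0.43, 3 above). Mesenchymal genes had a median of 0.09 in AGS, inside the range of random lists, beside 0.06 in HGC-27. The glycolysis and hypoxia list had a median of -0.00 in AGS, inside the range of random lists (-0.04 to 0.04). In all, 14 of 32 lists lay outside the central 95%, where 1.6 would by chance if the genes of a list varied independently of each other. The share simulated for HGC-27 with independent genes, 4 of 33, was above that rate, but some of those 33 lists held shifted genes. The highest ratios included those of EIF3C (1.09), U2AF1L5 (1.02), the cytoskeletal protein MAP1B (0.83), TRAM2-AS1 (0.82) and ANKRD1, and the 6 lowest those of PTPRO (-1.44), FGB (-1.01), YPEL2 (-0.98), FAM189A2 (-0.93), the cell cycle inhibitor CDKN1C (-0.87) and U2AF1 (-0.82). The difference between the responses of the lines was not tested for any gene or list, because 4 libraries leave no degree of freedom for it.

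**Figure D2:**
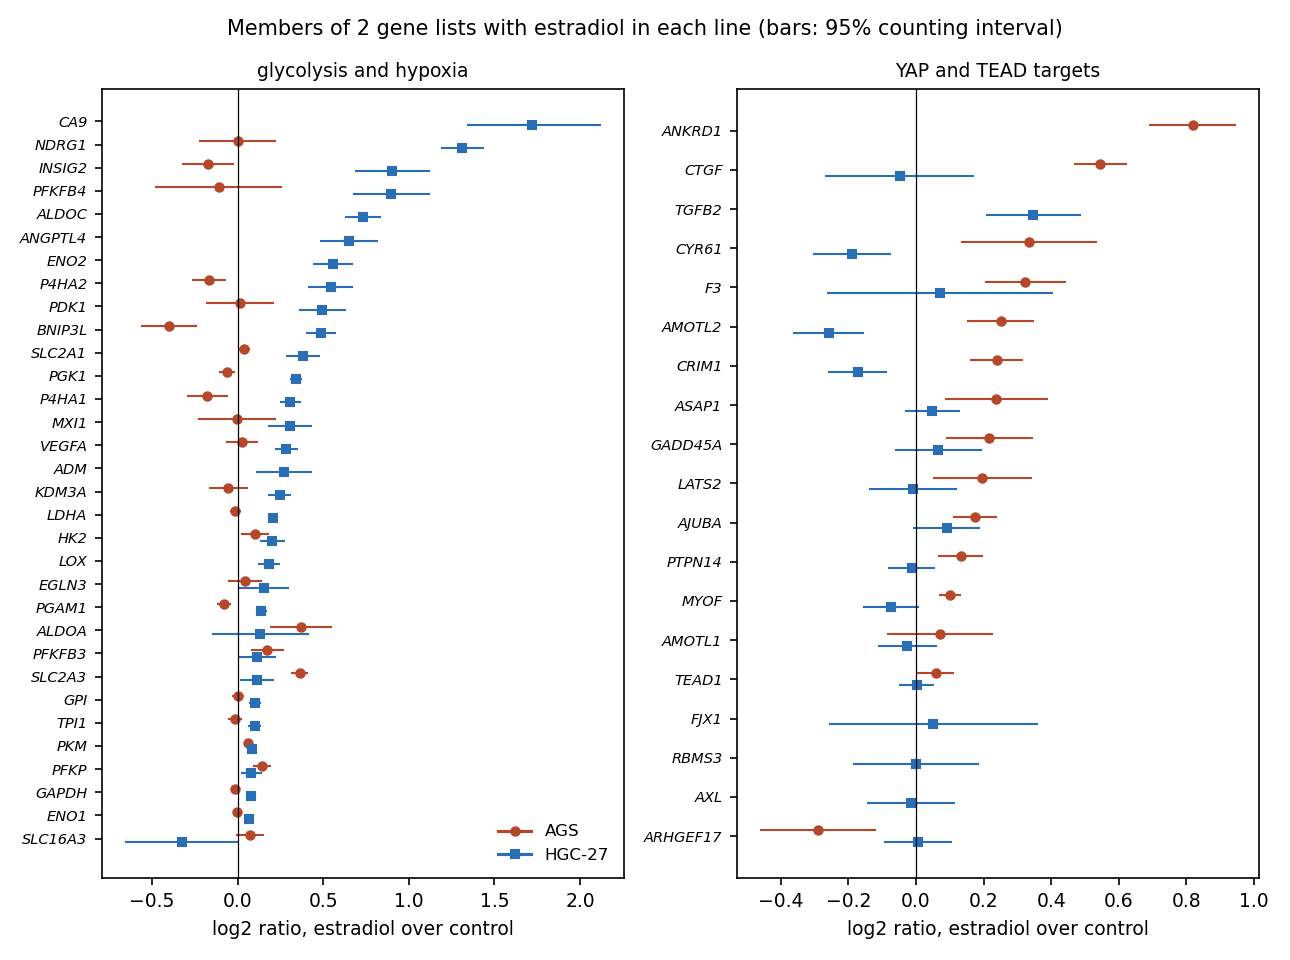
Log2 ratio of estradiol over control (horizontal axis) for members of the glycolysis and hypoxia list (left) and of the YAP and TEAD target list (right) in AGS (circles) and HGC-27 (squares); bars are 95% counting intervals, and a point is drawn where the line's mean count was at least 100. Hypoxia genes lie mostly above 0 in HGC-27 (median 0.26 over the members drawn) and around 0 in AGS, and YAP targets lie mostly above 0 in AGS (median 0.22 over the members drawn).

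The comparison of the lines with each other describes the background on which estradiol was tested. AGS expressed epithelial and gastric genes that HGC-27 lacked, and HGC-27 expressed matrix and mesenchymal genes that AGS lacked. The genes with the largest differences had 0 counts in both libraries of the other line, so their folds are lower bounds, taken against 3 counts over the other line's libraries. In AGS the aspartic protease CTSE (972 CPM in AGS) was at least 17464-fold higher, the creatine synthesis enzyme GATM at least 9254-fold, the membrane protein MAL2 at least 8900-fold, the transcription factor FOXQ1 at least 5128-fold and the adhesion molecule CEACAM6 at least 4717-fold. INAVA, UCA1, KIAA0040, LAD1 and TSPAN8 completed the 10 largest, the last at least 3646-fold higher. In HGC-27 the matrix protein POSTN was at least 10091-fold higher, the transcription factor TRPS1 at least 8054-fold, the cadherin CDH6 at least 7359-fold, the matrix protein SPARC at least 6943-fold and the collagen COL11A1 at least 6836-fold. QKI, BGN, EFHD1, the cell cycle inhibitor CDKN2A and EPB41L3 completed that set, the last at least 5093-fold higher. Of 18278 genes, 14106 (77.2%) passed the test, 6529 higher and 7577 lower in AGS (edgeR, same fit). The median over all genes was -0.10 on the log2 scale.

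Epithelial junction and keratin genes were higher in AGS for 45 of 46 members, with a median log2 difference of 7.20 (camera adjusted p = 3.01e-15). With an estimated correlation its adjusted p was 0.680, and none of the 17 called lists held. That correlation rests on 1 residual degree of freedom and called 0 of all 37 lists here. It therefore cannot tell lists that differ between the lines from lists that do not. The keratin KRT19 had 642 CPM in AGS and 0.06 in HGC-27. Gastric and intestinal identity genes were higher for 30 of 34 members, with a median of 7.08, or 5.86 with genes at 0 in HGC-27 set to their bound. Interferon-stimulated genes were higher for 30 of 38 (median 2.36), NF-kB genes for 17 of 24 (2.99), MAPK and immediate-early genes for 18 of 22 (1.77, DUSP4 at 9.25 ± 0.13) and p53 targets for 21 of 25 (1.60), among them the cell cycle inhibitor CDKN1A with 341 CPM against 14.4. Antigen presentation genes (median 0.69), apoptosis regulators (0.57) and endoplasmic reticulum chaperones (0.49) were also higher as lists. In the other direction, 36 of 42 mesenchymal genes were lower in AGS (median -7.48, or -7.13 with bounds), as were 29 of 35 HOX genes (-7.14, or -4.64 with bounds), 13 of 14 cancer-testis antigens (-9.67, or -9.44 with bounds) and 9 of 9 fibroblast and endothelial markers (-6.18), a list that shares POSTN, LUM and DCN with the mesenchymal list. ATF4 targets were lower in AGS for 28 of 31 members (-1.03), cholesterol genes for 21 of 26 (-1.21, SQLE at -3.60 ± 0.06), fatty acid synthesis genes for 15 of 22 (-1.13) and cytosolic ribosomal proteins for 66 of 85 (-0.55). The remaining 20 lists were not called (adjusted p 0.0714 to 0.989), and fry called 20 lists: 14 of the 17 and 6 others, losing endoplasmic reticulum chaperones (fry adjusted p = 0.0598), cholesterol genes (0.0613) and fatty acid synthesis genes (0.0598).

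**Figure D3:**
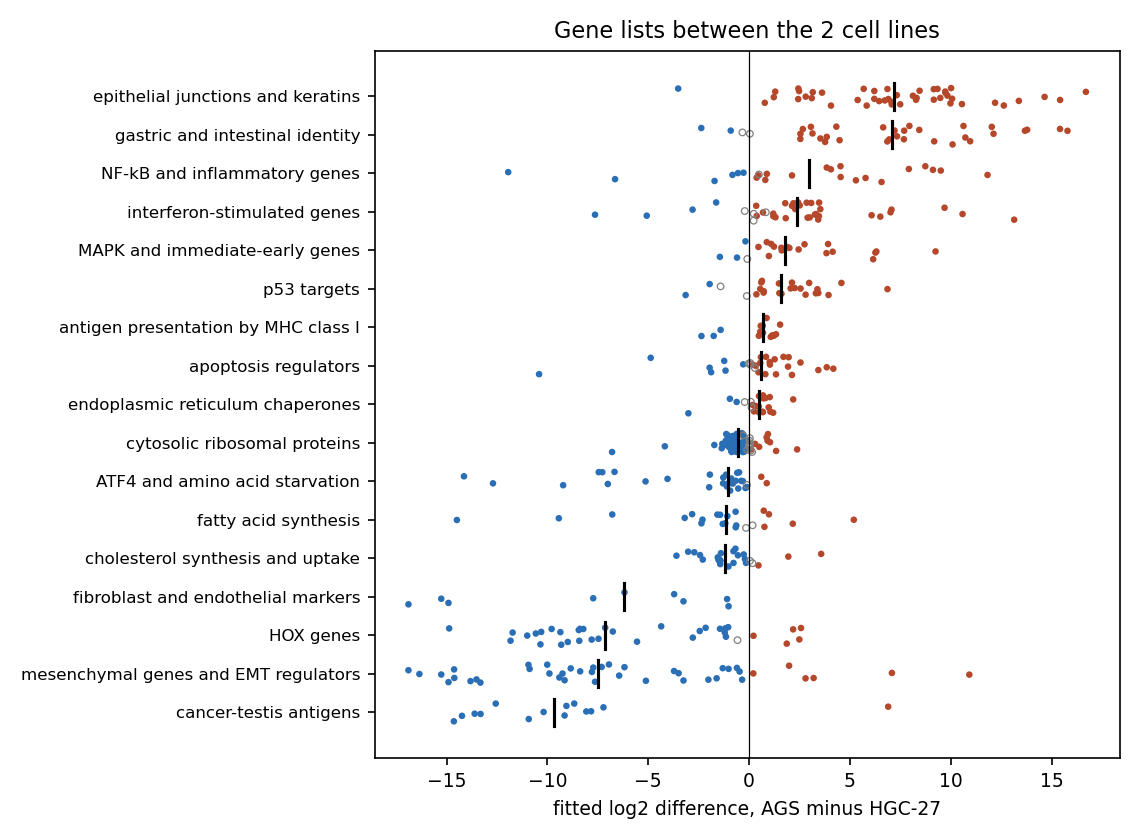
Fitted log2 difference of AGS minus HGC-27 (horizontal axis) for each tested member of the 17 lists called by camera; filled points passed the gene test, open points did not, and black bars are medians. Values of genes at 0 counts in 1 line are fitted values and no bounds; epithelial genes lie to the right (median 7.20) and cancer-testis antigens to the left (median -9.67).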

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

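The results here were picked because the lines moved in opposite directions with estradiol, each line being a single pair of libraries; the difference between the lines was not tested, and the screen and its size limit were chosen after the results were seen. Of 309 genes named by the rules, 38 had counting intervals on opposite sides of 0 in the lines, and 11 of these had ratios of at least 0.2 log2 in each line. Among 9867 genes with at least 100 mean counts in each line, 480 had intervals on opposite sides and 312 on the same side. Many of the named genes were picked by the size of their ratio in a line, which favours intervals without 0. GPR89B, one of a pair of near-identical copies, stood at -0.75 in AGS and 1.24 in HGC-27. The glycolytic enzyme ALDOC, which passed the test over both lines as higher, stood at -0.78 in AGS and 0.73 in HGC-27. The mTOR inhibitor DDIT4 stood at -0.56 in AGS and 0.54 in HGC-27, the mitophagy receptor BNIP3L at -0.40 and 0.49, and the iron exporter SLC40A1 at -0.48 and 0.24. The acetate-using enzyme ACSS2 stood at -0.38 in AGS and 0.42 in HGC-27, the sterol sensor INSIG1 at -0.27 and 0.24, and the interferon-induced exonuclease ISG20 at -0.47 and 1.45. The HGC-27 ratio of ISG20 rests on a mean count under 100. In the other direction, AMOTL2, a YAP target, stood at 0.25 in AGS and -0.26 in HGC-27, OSGIN1 at 0.31 and -0.34, and the MHC class I activator NLRC5 at 0.24 and -0.24.

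Of the gene lists, 4 lay outside the central 95% of random lists on opposite sides in the lines. Ribosome biogenesis factors had a median of 0.0645 in AGS and -0.129 in HGC-27. Cholesterol synthesis and uptake genes had a median of -0.107 in AGS and 0.0386 in HGC-27, fatty acid synthesis genes -0.0628 and 0.0329, and ferroptosis and iron genes -0.0678 and 0.0655. With members of at least 100 counts, fatty acid synthesis genes in AGS (-0.042) moved inside the range of random lists and so left this set. Ferroptosis and iron genes in HGC-27 fell to 0.0316 there.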

How the results depend on the processing

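The fit that leaves out genes of shared sequence and the agreement over genes with 100 counts in each line were added after seeing the data; the other settings were planned. The 21 higher and 7 lower estradiol calls became 9 and 4 with library totals, 1 and 0 with DESeq2, 0 and 0 with limma-voom, 0 and 0 with no replicate block, and 2 and 0 without the genes of shared sequence. Without the block the difference between the lines enters the spread, and the biological coefficient of variation was 109% in place of 4.59%. The prior degrees of freedom were 33.1 with library totals and 20.6 without the genes of shared sequence; the cause was not tested further. DESeq2 size factors (17 and 6), no filter (21 and 7) and a mean CPM of at least 1 (23 and 7) stayed within 1.5 times, sharing 23, 23 and 27 genes with the 28. Their prior degrees of freedom were 82.1 with DESeq2 size factors and infinite in the other cases. These settings thus also pool the spread over genes and are no independent check of the calls. STC1 turned to -0.39 with DESeq2, and other values moved by more than 1.5 times there, among them CA9 (0.12), ALDOC (0.02), ANKRD1 (0.19), FGB (-0.47), NRN1 (0.47) and LYZ (-1.05); the cause was not tested. Among called genes, either line alone gave ranges that crossed 0 for CTGF (-0.0481 to 0.54), ALDOC (-0.78 to 0.73), CFTR (-0.475 to 0.0700), NDRG1 (-0.00055 to 1.31) and ANKRD1 (-0.57 to 0.82). GREB1, which was not called, also crossed 0 (-0.441 to 0.889). A line with at most 3 counts of a gene gave no value. Of the 7 higher and 11 lower lists, 0 and 0 held with an estimated correlation, 0 and 0 with fry and 0 and 0 with no replicate block. With 4 libraries these settings can hardly detect small list changes, so 0 there does not show that a list was unchanged. With a mean CPM of at least 1 there were 8 and 6, and 13 of the 18 kept their call. For the lines, the 9 higher and 8 lower lists became 0 and 0 with an estimated correlation and 9 and 11 with fry. The estimated correlation rests on 1 residual degree of freedom and called 0 of all 37 lists there. Line calls ranged from 5766 to 6645 higher and from 6322 to 7744 lower, and the 20 named line genes kept direction and call in all settings. The same-sign share stayed between 48.1% and 48.2% and r between -0.01 and -0.00. Of 26 list medians within a line outside the central 95%, 26 stayed outside with library totals and 23 with members of at least 100 counts; fatty acid synthesis, NRF2 and MHC class I genes in AGS moved inside. The 24 ratios named within a line stayed inside their counting intervals with a prior of 5 counts and with library totals. Depth limits the values of genes expressed in 1 line, whose estradiol change rests on that line alone.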

Other observations

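Smaller groups of genes also differed between the AGS libraries. Genes of oestrogen synthesis and inactivation had a median log2 ratio of -0.18 over 15 members, with 5 counting intervals below 0 and 0 above. Of all AGS genes with a mean count of at least 100, 30.3% lay beyond theirs. AKR1C1, under the count minimum with 3 and 15 counts, stood at 2.06 (0.41 to 4.66). The steroid reductase AKR1C3 stood at -2.06 (-3.92 to -0.71) and the dehydrogenase HSD17B14 at -1.12 (-2.34 to -0.06). Aryl hydrocarbon receptor targets had a median of -0.18 over 7, with UGT1A6, which conjugates drugs, at -1.16 (-1.82 to -0.56) and CYP1A1, which hydroxylates estradiol, at -0.66 (-0.88 to -0.44). NRF2 and glutathione genes lay at -0.05 over 24 (also -0.05 in HGC-27, inside the range of random lists), with AKR1B10 at -2.19 (-3.34 to -1.28). AKR1C3 is a member of the first and the last of these lists. Endoplasmic reticulum chaperones lay at -0.06, with 11 of 23 intervals below 0 and 0 above, and antigen presentation genes at -0.07 over 15. Over members with at least 100 counts, the NRF2 (-0.04) and antigen presentation (-0.07) lists moved inside the range of random lists in AGS. In HGC-27, the lists of oestrogen synthesis and of aryl hydrocarbon receptor targets lay inside the range of random lists (medians -0.03 and -0.05). In HGC-27, heat shock genes had 10 of 20 intervals below 0 and 0 above, with the chaperone HSPH1 at -0.14 (-0.19 to -0.10). Nuclear respiratory chain genes had 20 of 82 below 0 and 3 above, where 26.1% of all HGC-27 genes with a mean count of at least 100 lay beyond theirs in either direction. The low median of replication-dependent histones in HGC-27 rested on few counts: 2 of 25 intervals lay below 0 and 3 above, with HIST2H2BF at 24 and 7 counts and HIST1H3G at 7 and 24.

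For the patterns that follow, the tests on GC content and on the spread of genes with near-identical copies were set down before their results were seen, and the others after. Glycolysis and hypoxia genes were higher in the HGC-27 estradiol library, with a median log2 ratio of 0.23. Removing the trend of all ratios on GC content and transcript length left 0.23 (0.227), above all random lists, which argues against such a trend. Of 21 genes abundant in AGS and nearly absent from HGC-27 control, the HGC-27 estradiol library showed 0.0161% of the AGS level (upper 95% limit 0.0224%), which argues against RNA of AGS cells. A nutrient, oxygen or density state of the HGC-27 estradiol dish cannot be told apart from estradiol with 1 dish per treatment: the ATF4 list, at 0.107, was higher in the same library, as either may produce. An effect of estradiol itself stays open and untested.

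YAP and TEAD targets were higher in the AGS estradiol library, with a median log2 ratio of 0.23. Removing the trend on GC content and length left 0.23 (0.230), above all random lists. Of 28 genes abundant in HGC-27 and nearly absent from AGS control, the AGS estradiol library showed 0.00371% of the HGC-27 level (upper 95% limit 0.00703%), so RNA of HGC-27 cells is argued against. YAP targets are known to respond to density and to fresh serum, and a density or medium state of the AGS estradiol dish cannot be told apart from estradiol, since 1 dish per treatment was sequenced; MAPK genes, at 0.0829, were higher in the same library, as either may produce. An effect of estradiol stays open and untested.

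Genes with near-identical copies were 9 of the 28 calls. For U2AF1 and U2AF1L5, the sum of the pair changed by at most 0.277 log2 in either line (AGS 0.28, HGC-27 0.07), while each gene changed by 0.82 or more in size, which is consistent with reads passing between the copies. For EIF3C the sum with EIF3CL still changed by 1.05 in AGS (0.96 to 1.14), which argues against reads passing between that pair in AGS; among the other families, sums moved less than the called gene for SMG1P2 (0.02 and 0.05), GTF2IP1 (-0.28 and -0.14), MTCO1P12 (-0.04 and 0.02) and MEMO1P1 (0.45 and 0.70), of which the first 3 have sums made up mostly of other members, and about as much for CCZ1B in HGC-27 (0.50). Genes that share at least 50% of their sequence lay beyond the counting interval more often than genes sharing under 5%, at matched counts, by ratios of 1.19 in AGS and 1.11 in HGC-27. Without matching on counts, their ratios had SDs of 0.263 against 0.147 in AGS and 0.228 against 0.141 in HGC-27, while their median absolute ratios at matched counts were no larger (0.109 against 0.124, and 0.109 against 0.113), which leaves open whether a greater spread is the source of these calls.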
